A study of Mus musculus with 7 samples.

How the data were processed

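Messenger RNA was measured on Agilent arrays that carry a red and a green dye. Per the labels' protocols, male mice with a tamoxifen-induced deletion of Acsl1 (Acsl1H-/-, 4 mice) and floxed control littermates (Acsl1flox/flox, 3 mice) were given tamoxifen at 75 mg/kg on 4 consecutive days at 6 to 8 weeks of age, and ventricles were frozen 10 weeks later. Total RNA was extracted from the ventricles. For each array, 500 ng of heart RNA was labelled with Cy-5 and 500 ng of a pool of whole newborn mouse RNA with Cy-3, and both were amplified with a low input kit, per the labels. Every array thus compared 1 heart with the same reference, with no dye swap among the samples used here. The labels call the samples of a group biological replicates. Whether the controls carry the recombinase is not given in the sources used here, so an effect of the recombinase cannot be set apart from the loss of Acsl1.

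The values used were the log2 ratios in the table the authors deposited, with 1 column per array and 7610 rows. The log base is not written there. Base 10 is excluded because the highest value, 8.81, lies above 4.82, the log10 of the range of a 16-bit scanner; the natural log is not excluded, and fold changes assume base 2. The direction, heart over reference, was taken from the dyes in the labels and checked with lists fixed in advance: 20 of 20 measured transcripts enriched in heart had a mean ratio above 0 (median 4.05), against 0 of 14 transcripts of other organs (median -4.51). The medians of the arrays lay between -0.03 and -0.01, so the values were centred before deposit. Background correction, normalization and the filter on rows are not given in the sources used here. Spot intensities and scanner flags were not analysed here, so it is not known which genes were dim, and a ratio from a dim spot is compressed toward the background. The number of arrays limits the precision.

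The row names join probe names and an Entrez gene ID, so the authors merged the probes of a gene before deposit; 5684 gene rows came from 1 probe and 1506 from several. Of the rows, 7190 had a gene ID and were tested, 390 were probes with no gene ID and 30 were control spots. A RefSeq gene table of assembly GRCm38.p6 gave the symbol of 7139 gene IDs and left 51 under their ID. The array's probe coordinates were not used here. There were no missing values, so the planned filter on missing values removed nothing. Closely related genes such as Gsta1 and Gsta2, or Acot1 and Acot2, can bind each other's probes, so their separate values are uncertain.

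Knockout and control ratios were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), and p-values were adjusted by Benjamini-Hochberg over the 7190 genes; a gene was called changed at an adjusted p below 0.05. Values are given as the log2 difference, knockout minus control, ± SE, with n = 4 knockout and n = 3 control hearts, unless stated otherwise. On simulated data with the same 7190 genes, this fit recovered 52% of genes changed 1.5-fold, 66% of those changed 2-fold, 92% at 4-fold and 98% at 8-fold, with 12 false calls among 170. Noise was drawn for each gene on its own and with the same spread in both groups. Variation shared between genes was thus not simulated.

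Before the data were examined, 53 gene lists were fixed for metabolic pathways, stress responses, growth signalling, heart muscle, cell types and RNA quality. The 47 with at least 5 measured members were tested with camera in limma at a preset correlation of 0.01, adjusted over the 47 lists. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move on balance one way and does not compare them with other genes. A gene can stand on several lists. Genes named by rule were Acsl1, the 10 largest rises and 10 largest falls among changed genes whose groups did not overlap, up to 4 members with the smallest p of each list described through its members, and a fixed set for the study's question (Acsl3, Acsl4, Acsl5, Acsl6, Pdk4, Nppa, Nppb, Myh7, Acta1, Ddit4, Asns and Mtor). Further genes are said to be named after their values were seen. Some genes that the rule selects are not reported here.

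The alternatives, whose effects the closing section gives, were centring each array, quantile normalization, testing all rows singly, a robust or trended prior, array weights, genes above the median ratio only, a 1.5-fold minimum, a permutation statistic after SAM, the replicate number as a block, and leaving out each sample in turn. Batch, slide and scan information is not given in the sources used here, so no batch was tested. Plots were drawn with matplotlib 3.10.9.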

Results

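The series measured gene expression in the heart ventricles of 7 male mice, 4 lacking Acsl1 in the heart and 3 floxed littermate controls, 10 weeks after tamoxifen. Acsl1 encodes the main long-chain acyl-CoA synthetase of the heart, which activates fatty acids for oxidation. The series title frames the question as how a heart that depends on glucose for energy alters metabolic genes under the control of mTOR, the kinase that couples nutrients to growth. The expression ratios of 7190 genes correlated at 0.93 to 0.95 between knockout hearts, at 0.952 to 0.958 between control hearts and at 0.90 to 0.922 between the groups. These correlations are across genes, which are not independent replicates. The median SD of a gene was 0.186 among the 4 knockout and 0.148 among the 3 control hearts.

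Acsl1 (Entrez gene 14081) was 9.08-fold lower in the knockout hearts, with a log2 ratio to the reference of -2.45 ± 0.17 (SD, n = 4) against 0.73 ± 0.05 (SD, n = 3) in controls (limma, adjusted p = 4.78e-05). All 4 knockout hearts had less Acsl1 than any control. This checks the genotype labels only if the 3 merged probes lie in the deleted part, and their position is not given in the sources used here. Of the other synthetases of the family, Acsl4 differed by 0.14 ± 0.22 and Acsl5 by 0.10 ± 0.25, neither past the threshold (adjusted p = 0.741 and 0.836). The sign of Acsl4 turned without knockout 1 (-0.03) and that of Acsl5 without control 3 (-0.23). Acsl3 and Acsl6 were not analysed here. Among 15 measured genes of acyl-CoA synthesis and fatty acid uptake, 2 rose, 1 fell and 12 were not past the threshold, against 3 and 2 adjusted over the list alone. Fabp3, the fatty acid binding protein of heart muscle, rose by 0.94 ± 0.08, and Dbi, which binds acyl-CoA, by 0.52 ± 0.09 (adjusted p = 0.00376 and 0.0276). Without any 1 sample, 1 of these genes passed as higher, and without knockout 3 the list had 2 fallen members. The list did not pass (camera, adjusted p = 0.765); its median (0.03) and the test pointed up and its mean (-0.13), which includes Acsl1, down.

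The secreted hormones Gdf15 and Fgf21 had the largest rises of the comparison, 37.8-fold and 30.0-fold (log2 5.24 ± 0.34 and 4.91 ± 0.17, adjusted p = 0.00106 and 4.78e-05). The glutathione transferase Gsta2 rose by 4.65 ± 0.46, the muscle nicotinamide riboside kinase Nmrk2 by 4.42 ± 0.35 and the mitochondrial folate enzyme Mthfd2 by 4.15 ± 0.47. Other large rises were in the stress-induced pseudokinase Trib3 (3.71 ± 0.57), Gsta1 (3.28 ± 0.35), the stress transcription factor Atf3 (3.20 ± 0.52) and Myh7, the slow myosin heavy chain (2.58 ± 0.15). After Acsl1, the largest falls were in the kinetochore gene Cenpf (-2.63 ± 0.22), the non-coding RNA Snhg14 (-2.46 ± 0.32), the zinc finger gene Zfp30 (-2.41 ± 0.39) and the microtubule-severing gene Fign (-1.82 ± 0.20). They were followed by Gm10336 (-1.55 ± 0.18), the tRNA methyltransferase Trmt5 (-1.51 ± 0.22), Mpped2 (-1.49 ± 0.10), Smim3 (-1.49 ± 0.20) and Zfp612 (-1.48 ± 0.22). In all, 327 genes changed, 165 higher and 162 lower, of which 53 rose and 36 fell at least 2-fold. The groups did not overlap in 1744 genes, 24.3% of those tested, where chance gives 5.71%. The count of changed genes depended on each sample: it was 185, 111, 215 and 104 without knockout 1, 2, 3 and 4, and 45, 76 and 74 without control 1, 2 and 3. In all 7 of these fits 32 genes stayed past the threshold, among them Acsl1, Fgf21, Gdf15, Gsta2, Gsta1, Nmrk2, Myh7, Cenpf, Fign, Mpped2 and Gm10336.

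**Figure D1:**
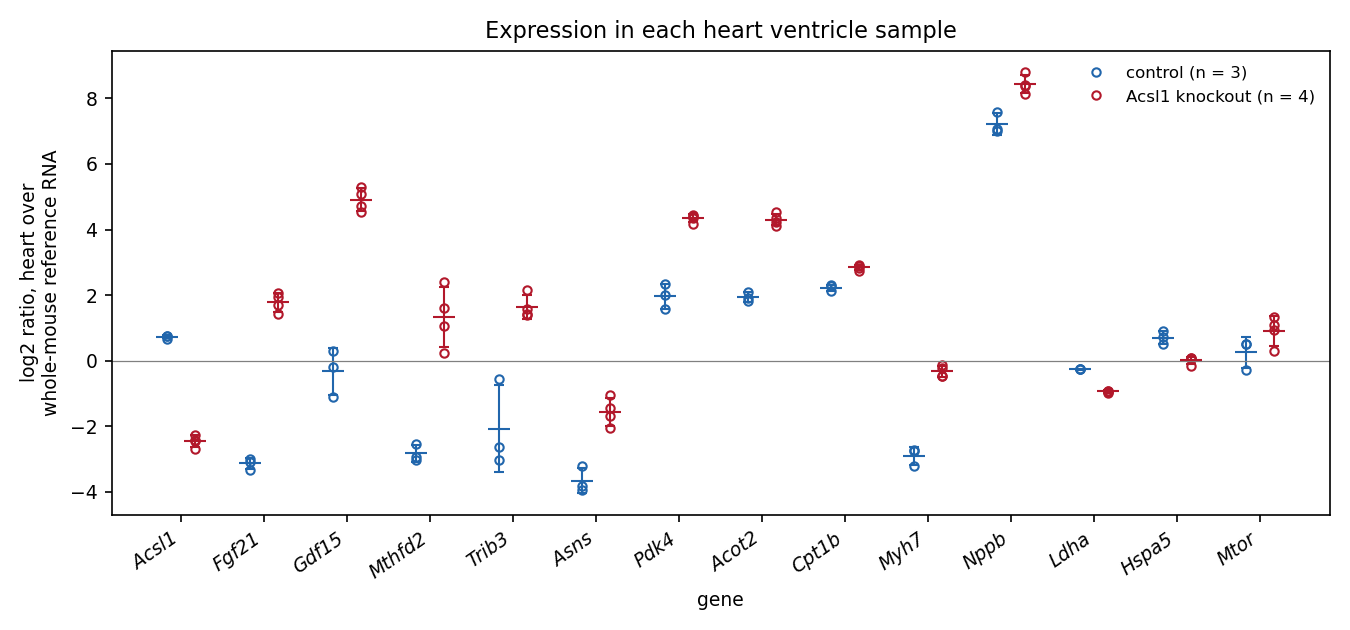
Log2 ratio of heart over whole-mouse reference RNA (vertical axis) for 14 genes (horizontal axis), with each circle a heart, horizontal marks the group means and bars the SD (blue, 3 controls; red, 4 Acsl1 knockouts). Acsl1 lies lower in all 4 knockout hearts, Fgf21 and Gdf15 higher, and the groups overlap for Mtor.

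Targets of PPARA, the nuclear receptor that switches on fatty acid oxidation, rose as a group: 9 of 23 measured members rose, 0 fell and 14 were not past the threshold, against 16 and 0 adjusted over the list alone. Beside Fgf21 these included Pdk4, the kinase that shuts off pyruvate dehydrogenase (5.20-fold, 2.38 ± 0.18, adjusted p = 0.00214), the mitochondrial acyl-CoA thioesterase Acot2 (2.36 ± 0.12, adjusted p = 0.000571) and Fabp3. The list passed with the preset correlation (median 0.46, adjusted p = 1.43e-11) and was the only 1 of 47 to pass with an estimated correlation as well (adjusted p = 0.0223). The count of risen members was 5 without control 1 or control 3 and 6 to 8 without any other sample. Genes of mitochondrial fatty acid oxidation also rose (3 of 24 rose, 0 fell, median 0.17, adjusted p = 0.000753, but adjusted p = 0.249 with an estimated correlation), with 9 risen and 1 fallen adjusted over the list alone. The risen members were Acot2, the dienoyl-CoA reductase Decr1 (1.07 ± 0.13) and Cpt1b, the muscle form of the enzyme that admits fatty acids to mitochondria (0.61 ± 0.09). Only Acot2 passed without control 1. Hadhb, of the trifunctional protein, differed by 0.39 ± 0.09 (adjusted p = 0.055). In the peroxisomal list, 3 of 19 genes rose and 1 fell, and the list did not pass (adjusted p = 0.11), but did without knockout 1 (adjusted p = 0.0348). Without knockout 2, knockout 4 or any 1 of the controls 0 members passed as higher, with 1 without knockout 1 and 2 without knockout 3, and 0 passed as lower without any 1 sample. Among them were Cat (0.56 ± 0.11), Ech1 (0.48 ± 0.09) and Scp2 (-0.40 ± 0.08), the last of which fell; Ech1 and Scp2 were named after their values were seen.

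Genes of lipid synthesis rose too. In the list for triacylglycerol and phospholipid synthesis 4 of 25 rose and 0 fell, against 4 and 1 adjusted over the list alone (median 0.19, adjusted p = 0.0266, but adjusted p = 0.249 with an estimated correlation). These were Gpam, which starts glycerolipid synthesis (0.73 ± 0.09), the acyltransferases Agpat3 (0.54 ± 0.07) and Lpcat3 (1.11 ± 0.18), and Pcyt2, of phosphatidylethanolamine synthesis (0.39 ± 0.08). The list lost its call without knockout 3 (adjusted p = 0.0545) and without control 2 (adjusted p = 0.0657), and 1 member passed without any 1 of the controls. Of 11 genes of fatty acid synthesis and desaturation, 2 rose and 0 fell, against 5 and 1 adjusted over the list alone (median 0.27, adjusted p = 0.00378, but adjusted p = 0.274 with an estimated correlation). They were Srebf1, the transcription factor of lipid synthesis (2.33-fold, 1.22 ± 0.12, adjusted p = 0.00532), and Mlycd, which degrades malonyl-CoA and so works against synthesis (0.52 ± 0.10). Without any 1 sample, 1 member passed. The desaturase Scd2 differed by 0.82 ± 0.19 and Mid1ip1 by -0.57 ± 0.13, neither past the threshold. Of 15 sterol synthesis genes, 0 passed in limma or adjusted over the list alone and 8 had an unadjusted p under 0.05 (list adjusted p = 0.691); without knockout 3, 1 passed as higher. In the lipid droplet list 1 of 11 rose, Plin5, which coats droplets in oxidative tissue (0.49 ± 0.08, named after its value was seen), and the list did not pass (adjusted p = 0.857) and had 0 risen members without knockout 2, knockout 4 or any 1 of the controls, and 2 without knockout 3; its median (0.01) and the test pointed up and its mean (-0.02) down.

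Targets of ATF4, the transcription factor of the amino acid response, held most of the largest rises. Of 27 measured members 10 rose, 0 fell and 17 were not past the threshold, against 11 and 0 adjusted over the list alone (median 0.40, adjusted p = 6.97e-07, but adjusted p = 0.171 with an estimated correlation). Beside Gdf15, Fgf21, Mthfd2, Trib3 and Atf3, the amino acid transporter Slc7a5 rose 4.03-fold (2.01 ± 0.14), the glutathione-degrading Chac1 by 2.15 ± 0.25 and the asparagine synthetase Asns by 2.09 ± 0.27. The remaining risen members, Atf5 (1.04 ± 0.17) and Ddit3 (2.04 ± 0.42), both stress transcription factors, were named after their values were seen. The count of risen members was 4 without control 1, 6 without control 2, control 3 or knockout 4, and 7 to 10 otherwise. Of 21 aminoacyl-tRNA synthetases, which charge tRNAs for translation, 5 rose and 0 fell, against 8 and 0 adjusted over the list alone (median 0.23, adjusted p = 0.00378, but adjusted p = 0.257 with an estimated correlation). Iars (0.66 ± 0.11), Sars (0.59 ± 0.10), Nars (0.57 ± 0.11), Aars (0.51 ± 0.10) and Lars (0.43 ± 0.09, named after its value was seen) were the risen members. Without knockout 1 or knockout 3, 2 of them passed, and 0 without any other sample. The list for serine, glycine and one-carbon metabolism did not pass (adjusted p = 0.091), but did without control 3 (adjusted p = 0.0459), with 2 of 17 risen, Mthfd2 and Sardh (1.48 ± 0.28), and 1 fallen, the methionine adenosyltransferase Mat2a (-0.48 ± 0.09); Sardh and Mat2a were named after their values were seen. Of that list 0 members passed as higher without control 1 and 1 without control 2 or knockout 2, 3 or 4, and 0 passed as lower without any 1 sample.

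Of 30 glutathione genes 3 rose and 0 fell, against 7 and 1 adjusted over the list alone (median 0.13, adjusted p = 0.0255, but adjusted p = 0.249 with an estimated correlation). These were Gsta2 and Gsta1, which conjugate glutathione to reactive compounds, and Chac1, which degrades it, while the peroxidase Gpx4 differed by 0.35 ± 0.08 (adjusted p = 0.0546). The list lost its call without knockout 2 (adjusted p = 0.051). Targets of NFE2L2, the antioxidant transcription factor, rose in 4 of 31 and fell in 1, against 5 and 2 adjusted over the list alone (median 0.15, adjusted p = 0.0231, but adjusted p = 0.341 with an estimated correlation). Aldehyde oxidase Aox1 (1.00 ± 0.16), ferritin light chain Ftl1 (0.71 ± 0.13), catalase Cat (0.56 ± 0.11) and the quinone reductase Nqo1 (0.98 ± 0.19, named after its value was seen) rose, and the efflux pump Abcc1 fell by 0.81 ± 0.14. That list lost its call without knockout 2 (adjusted p = 0.0516) and without control 2 (adjusted p = 0.0708), and 0 members passed without knockout 4 or without any 1 of the controls (as higher, 2 passed without knockout 1 and 1 without knockout 2).

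Genes of glucose uptake and glycolysis were lower: 0 of 25 rose and 3 fell, and the same numbers passed adjusted over the list alone (median -0.17, adjusted p = 0.0159, but adjusted p = 0.371 with an estimated correlation). Ldha, the lactate dehydrogenase subunit, fell by 0.68 ± 0.07 (1.60-fold lower, adjusted p = 0.00647), the basal glucose transporter Slc2a1 fell by 0.48 ± 0.09 (adjusted p = 0.0336) and the muscle enolase Eno3 fell by 0.42 ± 0.08 (adjusted p = 0.0409). Ldhb differed by -0.23 ± 0.08 and did not pass. In each fit without 1 sample, 1 glycolytic gene passed. Of 30 genes of pyruvate oxidation and the citric acid cycle, 1 rose, Pdk4, and 0 fell, while 25 had a negative difference (median -0.14, adjusted p = 0.0231, but adjusted p = 0.529 with an estimated correlation). This call ended without knockout 1 (adjusted p = 0.0954) and without knockout 2 (adjusted p = 0.0603). Oxidative phosphorylation showed small shifts: 45 of 55 genes had a negative difference, 0 rose and 1 fell (median -0.09, adjusted p = 0.0038, but adjusted p = 0.356 with an estimated correlation). The fallen gene was Cox7a1, the heart and muscle subunit of cytochrome oxidase (-0.57 ± 0.08, named after its value was seen), and 0 genes passed without control 1 or control 2. The list of hypoxia genes did not pass (adjusted p = 0.0545), but did without control 1 (adjusted p = 0.0213) or control 3 (adjusted p = 0.0451), with Hif1a, the oxygen-regulated transcription factor, higher by 1.15 ± 0.15, Ldha and Slc2a1 lower, and Bnip3 at -0.56 ± 0.13 without passing. Without any 1 of the controls 0 hypoxia genes passed as higher, and 1 passed as lower without any sample other than knockout 1. Glycogen genes did not pass as a list (adjusted p = 0.642), with 1 of 14 fallen, the glycogen-targeting phosphatase subunit Ppp1r3a (-0.90 ± 0.18, named after its value was seen), and 0 without any 1 sample. The pentose phosphate list had 0 of 12 genes past the threshold in limma, adjusted over the list alone or at an unadjusted p under 0.05 (list adjusted p = 0.998), with a negative median (-0.06) and mean (-0.04) though the test pointed up.

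Components and regulators of the mTOR complex did not pass as a list (39 measured, 0 rose, 2 fell, median -0.09, camera, adjusted p = 0.431), with 2 risen and 5 fallen adjusted over the list alone. The list holds both activators and inhibitors, so a test for a common direction can miss changes that oppose each other. The fallen genes were Sesn1, an inhibitor of the complex (-0.82 ± 0.10, adjusted p = 0.0134), and Akt1, a kinase that activates it (-0.36 ± 0.07, adjusted p = 0.0419). The count of fallen genes was 0 without any 1 of the controls and 1 without knockout 1, 2 or 4, and without knockout 3 it was 2, with 1 risen. Mtor itself differed by 0.66 ± 0.30 (adjusted p = 0.238) and its stress-induced inhibitor Ddit4 by -0.55 ± 0.39 (adjusted p = 0.437), neither past the threshold. Without control 1 Mtor differed by 0.39 and Ddit4 by -0.87, and without knockout 3 Ddit4 differed by -0.33. Insr (-0.62 ± 0.14) and Pik3ca (-0.41 ± 0.09) did not pass, but without knockout 3 Insr did (-0.73, adjusted p = 0.0315). The activity of the kinase was not measured. Transcript levels of its components and regulators therefore do not answer whether mTOR controls the genes that changed. Genes of the translation machinery were slightly higher. Of 74 ribosomal protein genes 71 had a positive difference and 2 rose, Rps2 (0.55 ± 0.08) and Rpl10a (0.43 ± 0.09), both named after their values were seen (median 0.15, adjusted p = 1.45e-10, but adjusted p = 0.371 with an estimated correlation). Of them, 1 passed without knockout 1, and 0 without knockout 2, knockout 4 or any 1 of the controls. Translation factors had 0 of 31 genes past the threshold in limma or adjusted over the list alone and 10 at an unadjusted p under 0.05, yet passed as a list (median 0.13, adjusted p = 0.00378, but adjusted p = 0.171 with an estimated correlation). In ribosome biogenesis, 1 of 24 genes rose, the growth transcription factor Myc (5.11-fold, 2.35 ± 0.37, adjusted p = 0.0234), and 1 fell, Taf1d (-1.31 ± 0.19), both named after their values were seen, and the list did not pass (adjusted p = 0.159). As higher, 0 passed without knockout 1, control 1 or control 3, and as lower, 0 passed without control 1 or knockout 4 and 2 without knockout 1. In the atrophy list driven by FOXO factors 0 of 16 rose and 2 fell, Sesn1 and the muscle ubiquitin ligase Fbxo32 (-1.04 ± 0.22, adjusted p = 0.0449), while Gadd45a differed by 0.51 ± 0.11 without passing, as did the list (adjusted p = 0.374). After quantile normalization Fbxo32 did not pass (-0.98, adjusted p = 0.0558). Without any 1 of the controls 0 of the fallen genes passed, and 1 without knockout 1 or knockout 4. Autophagy and lysosome genes had 0 of 31 past the threshold in limma or adjusted over the list alone and 4 at an unadjusted p under 0.05 (list adjusted p = 0.998), with a median just below 0 and a mean just above.

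Genes of protein folding in the endoplasmic reticulum were lower, with a negative difference in 18 of 20, 0 risen and 1 fallen, against 0 and 3 adjusted over the list alone (median -0.23, adjusted p = 0.0012, but adjusted p = 0.171 with an estimated correlation). The chaperone Hspa5 fell by 0.69 ± 0.12 (1.62-fold lower, adjusted p = 0.0294). It was the 1 fallen member, and 0 members passed without any 1 sample except control 3. Atf6, a sensor of unfolded protein, differed by -0.45 ± 0.12, the ubiquitin ligase Syvn1 by -0.28 ± 0.07 and the chaperone Hsp90b1 by -0.26 ± 0.07, none past the threshold.

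In the list of hypertrophy and fetal heart genes 5 of 22 rose and 0 fell, against 5 and 2 adjusted over the list alone. Myh7 rose 5.96-fold (adjusted p = 0.000981), the natriuretic peptide Nppb 2.31-fold (1.21 ± 0.20, adjusted p = 0.0265) and the skeletal actin Acta1 1.99-fold (1.00 ± 0.16, adjusted p = 0.0234), beside Gdf15 and Nmrk2. After quantile normalization Nppb differed by 0.52 and did not pass (adjusted p = 0.164). Nppb was the highest value in every knockout heart and in control 3. Quantile normalization gives the highest value of each array the same number, so it shrinks this difference by construction. Nppb also did not pass without knockout 1, 2 or 3 or control 1 or 2 (adjusted p = 0.0539, 0.0531, 0.053, 0.0903 and 0.0925). Nppa, the atrial peptide, differed by 0.53 ± 0.19 (adjusted p = 0.159). The list did not pass (adjusted p = 0.111), but did without knockout 4 (adjusted p = 0.0371), and its median (-0.01) lay below 0 while its mean (0.60) and the test pointed up; 3 members passed without knockout 2, control 1 or control 2. Genes of the adult sarcomere were lower (23 measured, 1 rose, 2 fell, median -0.12, adjusted p = 0.027, but adjusted p = 0.415 with an estimated correlation), with 1 and 3 adjusted over the list alone. The M-band genes Myom2 (-1.22 ± 0.15) and Myom1 (-0.46 ± 0.07) fell and the small heat shock protein Cryab rose (0.46 ± 0.07), while Tcap, of the Z-disc, differed by -0.56 ± 0.15 without passing. The sarcomere call ended without knockout 1 (adjusted p = 0.077), knockout 4 (adjusted p = 0.076), control 1 (adjusted p = 0.0571) and control 3 (adjusted p = 0.0578). Without any 1 of the controls 0 sarcomere genes passed, and without knockout 2 or knockout 4 1 passed as lower and 0 as higher. Of 24 genes of calcium handling and ion channels 0 rose and 2 fell, against 0 and 8 adjusted over the list alone (median -0.28, adjusted p = 0.00164, but adjusted p = 0.371 with an estimated correlation). The potassium channel Kcnj12 fell by 1.28 ± 0.20. The count of fallen genes was 0 without any 1 of the controls, 1 without knockout 2 or knockout 4, 2 without knockout 1 and 3 without knockout 3. The potassium channels Kcnj11 (-0.95 ± 0.22) and Kcnq1 (-0.83 ± 0.20) did not pass, although Kcnj11 did without knockout 3 (-1.11, adjusted p = 0.0365).

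**Figure D2:**
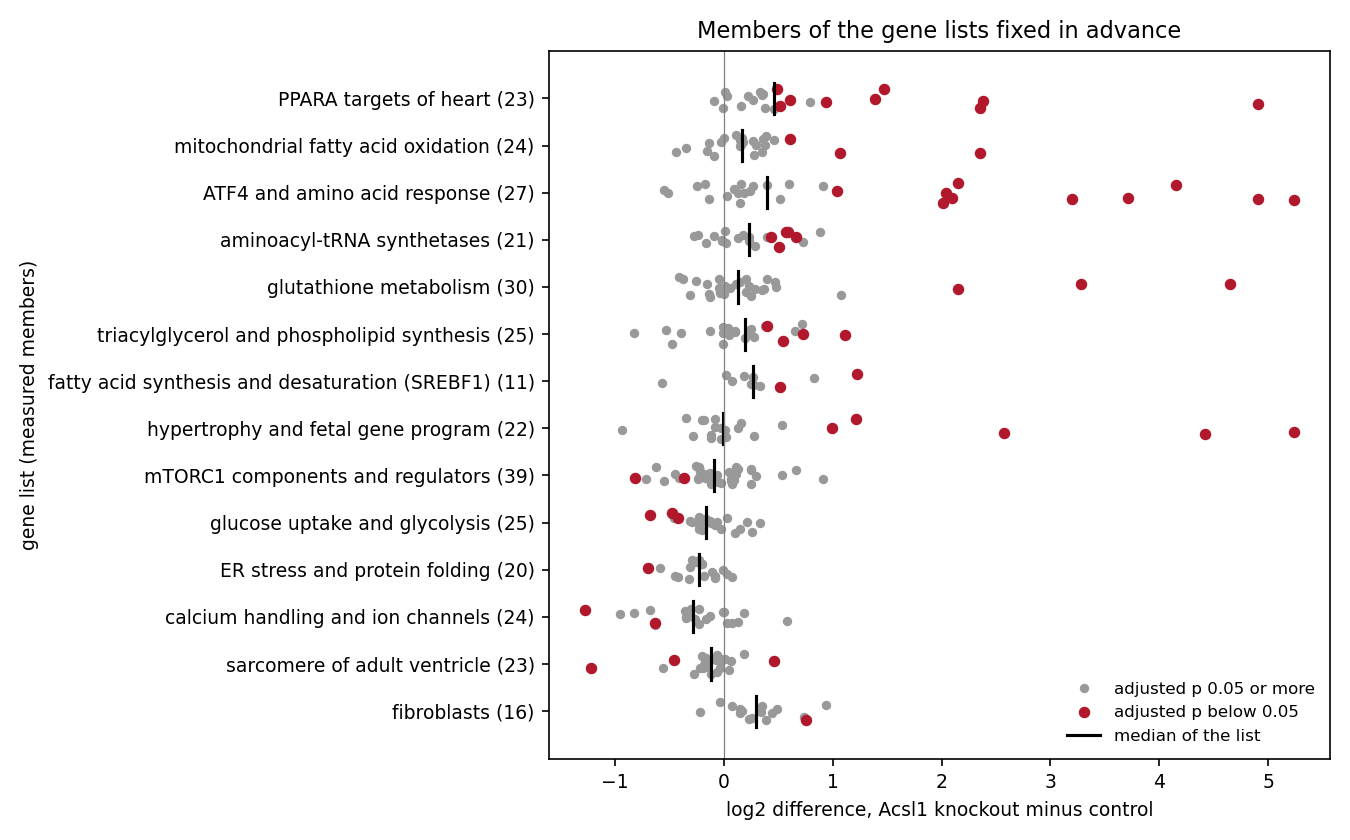
Log2 difference, knockout minus control (horizontal axis), of each measured member of 14 gene lists (vertical axis, number of measured members in brackets). Red points passed an adjusted p of 0.05, grey points did not, and black bars are list medians. The red points of the PPARA and ATF4 lists all lie above 0, those of the glycolysis list below 0.

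Of 16 fibroblast genes 14 had a positive difference and 1 rose, the dipeptidase Dpep1 (0.75 ± 0.12), as it did adjusted over the list alone (median 0.30, adjusted p = 0.00439, but adjusted p = 0.415 with an estimated correlation). Pdgfra (0.73 ± 0.20), Fbln1 (0.94 ± 0.30) and Gsn (0.49 ± 0.18) did not pass, although Fbln1 did without knockout 1 (0.65, adjusted p = 0.0474). The count of risen fibroblast genes was 0 without knockout 2, knockout 4, control 1 or control 3, and 2 without knockout 1. Of 31 extracellular matrix genes 27 had a positive difference and 1 rose, the matrix glycoprotein Thbs4 (0.88 ± 0.16), as it did adjusted over the list alone (median 0.23, adjusted p = 0.0042, but adjusted p = 0.445 with an estimated correlation). Mmp2 (0.57 ± 0.21), Mmp14 (0.31 ± 0.11) and Dcn (0.38 ± 0.16) did not pass. Without any 1 sample except control 2, 0 matrix genes passed. The mean of the fibroblast list, set against the control mean, was 0.67 in knockout 1 and 0.15 to 0.31 in the other knockout hearts. In limma 0 genes passed in the lists for endothelial cells (20 measured, adjusted p = 0.144), smooth muscle and pericytes (13, adjusted p = 0.693), macrophages (15, adjusted p = 0.206, but 0.0175 without control 2), erythroid cells (7, adjusted p = 0.453), adipocytes (6, adjusted p = 0.307) and atrial muscle (6, adjusted p = 0.503). At an unadjusted p under 0.05 these lists held 1, 3, 2, 0, 2 and 3 genes in that order, and of them only adipocytes had members past the threshold adjusted over the list alone (2 risen). Without knockout 3, 1 adipocyte gene passed as higher and 1 gene of smooth muscle and pericytes as lower. Lists for lymphocytes and granulocytes, epicardium, neurons, other organs, Y-linked genes and Xist had under 5 measured members and were not tested.

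Of 14 immediate early genes, which respond within minutes to stimuli that include dissection, 3 rose and 0 fell, against 6 and 1 adjusted over the list alone (median 0.40, adjusted p = 0.00912, but adjusted p = 0.42 with an estimated correlation). These were Atf3, Jun (0.72 ± 0.13) and Ier2 (0.79 ± 0.15), while Egr1 differed by 1.79 ± 0.46 (adjusted p = 0.0747). The call ended without control 2 (adjusted p = 0.0654). The count of risen genes was 0 without knockout 2, knockout 4, control 2 or control 3 and 1 without any other sample, and 1 gene passed as lower without knockout 3. Heat shock genes had 1 of 14 risen, Cryab, and 0 fallen, against 5 and 0 adjusted over the list alone (median 0.20, adjusted p = 0.0234, but adjusted p = 0.371 with an estimated correlation), and lost the call without knockout 1 (adjusted p = 0.0503) or control 1 (adjusted p = 0.147); 0 heat shock genes passed without knockout 2, knockout 4 or any 1 of the controls. Interferon response genes had 1 of 19 risen, Gbp2 (1.06 ± 0.17, named after its value was seen), and 0 fallen, against 3 and 0 adjusted over the list alone (median 0.32, adjusted p = 0.00523, but adjusted p = 0.42 with an estimated correlation), and 0 passed without knockout 2, knockout 4, control 1 or control 3.

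The other lists did not pass. In the p53 list, 1 of 16 genes rose (Plk2, 0.80 ± 0.11) and 2 fell (Sesn1 and Perp, -0.40 ± 0.08). In mitochondrial biogenesis, 1 of 27 fell (Gabpa, -0.67 ± 0.13), and in branched-chain amino acid and ketone breakdown 1 of 23 (Ivd, -0.48 ± 0.10). Plk2, Perp, Gabpa and Ivd were named after their values were seen. Without any 1 of the controls 0 genes of these lists passed as lower, and without control 1 0 p53 targets passed as higher. Without any 1 of the knockouts 1 p53 target passed as lower, 0 biogenesis genes passed, and 0 genes of branched-chain breakdown passed except without knockout 1. Acta1 was the 1 gene of 12 on the skeletal muscle list that rose; its median (-0.09) and the test pointed down and its mean (0.01) up, and 0 genes passed without knockout 2 or any 1 of the controls. In limma 0 genes passed for the circadian clock (10 measured), cell cycle (10) and mitochondrial dynamics (18), against 4, 2 and 4 at an unadjusted p under 0.05. Adjusted over the list alone, 1 clock gene rose and 3 fell, 1 gene of mitochondrial dynamics rose and 2 fell, and 0 cell cycle genes passed. Of the clock, 1 gene passed as higher without knockout 3, and of mitochondrial dynamics 1 as lower. The adjusted p of these lists was 0.857 for p53 targets, 0.127 for biogenesis, 0.111 for branched-chain breakdown (but 0.0329 without knockout 3), 0.816 for skeletal muscle, 0.374 for the clock, 0.967 for the cell cycle and 0.514 for mitochondrial dynamics. In total 21 of 47 lists passed with the preset correlation, 15 toward higher and 6 toward lower values, and 1 passed with an estimated correlation. Fry also called 21 lists, of which 15 were the same. It did not call pyruvate oxidation and the citric acid cycle (fry, adjusted p = 0.188), the sarcomere (0.0585), extracellular matrix (0.165), interferon response (0.115), fibroblasts (0.0825) or immediate early genes (0.0805). In their place it called peroxisomal fatty acid oxidation (0.0398), serine and one-carbon metabolism (0.0426), FOXO targets (0.0477), hypertrophy genes (0.0107), hypoxia genes (0.0271) and endothelial cells (0.0243).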

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

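The tests of fibroblast genes in this part were chosen only after the result was seen; the splits of the samples were planned.

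In 7 of 119 selected genes (5.88%, where chance gives about 5%), 1 knockout heart lay far from the other 3. Knockout 1 stood apart in Trmt5 (1.85 against 1.03 to 1.08), Nars (0.0194 against 0.27 to 0.32), Dcn (0.42 against -0.14 to -0.10) and Gsn (2.43 against 1.74 to 1.84). Knockout 3 stood apart in Cat (1.15 against 0.82 to 0.86) and in Scp2 (0.24 against 0.12 to 0.13), and knockout 2 in Hspa5 (-0.16 against 0.05 to 0.09). These are log2 ratios to the reference.

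Of the 390 probes with no gene ID, which enter no gene comparison, 28 changed (limma over all rows except control spots), 25 higher and 3 lower. Probe A_51_P305138 rose by 4.38 ± 0.30 and A_52_P1083765 by 1.74 ± 0.27, while A_52_P497715 fell by 0.87 ± 0.17 and A_52_P443435 fell by 0.52 ± 0.09.

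Splits of the 7 samples argue against chance as the source of the gene count but cannot exclude it. With 35 splits, 1 of 35 is the smallest share possible. Every split other than the genotype split mixes the genotypes, so a true difference widens its groups and lowers its count. Among the 35 splits of the 7 samples into 4 and 3, 1 gave 327 changed genes, the genotype split itself, and the highest of the other splits gave 1 gene. For gene lists, 1 of the 35 splits gave 21 lists, again the genotype split, and the highest of the other splits gave 16. In 2 splits the count was 16, and both set 3 knockout hearts against the remaining knockout and the 3 controls. Splits that put 2 controls among the 4 hearts of the larger group, and so mix the genotypes almost evenly, still gave up to 9 lists. The preset correlation thus calls some lists without a clear genotype contrast.

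The combined score of fibroblast and matrix genes differed by 0.267 between knockout and control hearts, with a 95% interval (-0.0816 to 0.615) that includes 0, and Dcn and Gsn of these lists were extreme in knockout 1. That heart may carry part of the pattern: without it the mean of the fibroblast list fell from 0.325 to 0.209, or 0.643 of its value, although the list stayed past the preset-correlation threshold without any 1 sample. A lower share of heart muscle cells would raise endothelial and mural markers alike. The combined fibroblast and matrix score exceeded the endothelial and mural score by 0.233 (95% interval -0.0761 to 0.541), so a lower muscle share and a change in fibroblasts cannot be told apart with 7 hearts whose fibroblast scores vary this much. Growth of fibroblasts after the loss of Acsl1 stays open as a biological explanation.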

How the results depend on the processing

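The overlap of lists was examined after the data were seen; all other alternatives were planned. The 327 changed genes became 213 with a 1.5-fold minimum, which by construction removes smaller changes, and 10 with the replicate number as a block. The block also spends terms on the replicate numbers, which leaves a weaker test. The values showed no sign that numbers pair the hearts. Deviations of same-numbered hearts correlated at 0.002, 0.053 and 0.014, and 1 of the 3 controls correlated best with the knockout of its own number. So few correlations cannot exclude a pairing. Leaving out 1 sample gave 45 to 215 genes, as fewer samples give a weaker test, with 0 sign changes among the 327. The other 8 alternatives gave 305 to 443, and 188 to 327 of the 327 genes kept their call. The 188 came from testing only genes above the median ratio, which leaves the other genes untested. The permutation statistic kept 269. Acsl1 stayed past the threshold wherever tested (-3.11 to -3.25 without 1 sample). Acsl4 turned sign without knockout 1 (-0.0317 to 0.271 without each sample) and Acsl5 without control 3 (-0.229 to 0.288); neither passed in any setting and the cause was not tested. Of the 118 other selected genes, 29 to 67 lost their call without 1 sample. Some of the 118 had no call to lose, so the share of calls lost is larger than these counts out of 118. After quantile normalization Nppb (0.516, adjusted p = 0.164), whose difference that method shrinks by construction, and Fbxo32 (-0.981, adjusted p = 0.0558) lost their call. So did Pcyt2 and Rpl10a with a trended prior, Lars with a robust prior, and Eno3, Pcyt2, Aars, Akt1, Lars, Scp2, Ech1, Mat2a, Ivd, Rpl10a and Perp with the permutation statistic. Gene lists past the threshold went from 21 to 1 with an estimated correlation (the cause was not tested) and were 16 with the block and 18 to 22 otherwise. Estimates were below the preset 0.01 for endoplasmic reticulum folding (-0.024), triacylglycerol and phospholipid synthesis (-0.025), glutathione (-0.016) and translation factors (-0.013). These lists lost their calls too, so a higher correlation among their own members was not why. The other lists that lost their calls had estimates above the preset value, such as ribosomal proteins (0.27). Without the 2 members they share, the PPARA list (8 of 21 rose, adjusted p = 1.45e-10) and the ATF4 list (9 of 25, adjusted p = 7.23e-06) kept their calls. The planned choice of the probe with the highest ratio was not run, since probes were merged before deposit, and both filters on missing values changed nothing. Signal over background was not analysed here, so its limit on dim genes is unknown.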

Other observations

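The tests of zinc finger genes and of explanations for the rise of ATF4 targets were chosen only after the result was seen, and so were the genes named here for the first time; the limma fit and the leaving out of samples were planned.

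Some regulators changed too, as single genes. Of these, Hif1a stands on the hypoxia list, which did not pass with the preset correlation (camera, adjusted p = 0.0545). Ppara fell by 0.84 ± 0.14 (adjusted p = 0.0276) while its targets rose, and Hif1a rose while the hypoxia-induced Ldha and Slc2a1 fell. Fbxw7, the ubiquitin ligase subunit that marks MYC, SREBP and mTOR proteins for degradation, fell by 1.33 ± 0.12 (adjusted p = 0.00447); protein levels were not measured. Among PPARA targets, Acot1 (1.39 ± 0.12) and Angptl4 (1.47 ± 0.29), which inhibits lipoprotein lipase, also rose.

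Other genes with firm changes belonged to none of the themes above. The water channel Aqp8 rose by 2.40 ± 0.17 and the survival gene Bcl2 by 1.17 ± 0.11. Crhr2, the heart's receptor for urocortins, fell by 1.23 ± 0.13. All 3 passed the threshold without any 1 of the 7 samples.

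Zinc finger genes fell more often than others. Of 108 genes whose symbol starts with Zfp and a digit, 84 had a negative difference, 11 fell and 0 rose (median -0.21), among them Zfp30, Zfp612, Zfp687 (-1.06 ± 0.18) and Zfp410 (-1.10 ± 0.23), whereas 151 of the 7082 other genes fell (Fisher's exact test across genes, p = 2.83e-05). The tables argue against a trend with gene length or with the level against the reference: at most 0.01% of 10000 lists matched on both had so low a median, the smallest share the draws can give, and their medians centred on -0.01. The mean over these genes was lower in all 4 knockout hearts than in any control (two-sided exact permutation p = 0.0286, the smallest possible with 35 splits). The family was picked after its falls were seen in these same hearts, so neither this p nor the Fisher p is independent support. A lower output of this family in knockout hearts is a hypothesis, and probe quality and normalization before deposit stay open.

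The rise of ATF4 targets has several candidate explanations. Stress of the endoplasmic reticulum, a known trigger of ATF4, would raise its genes of protein folding. The mean of that list, which holds chaperones and other genes, differed by -0.241 (95% interval -0.357 to -0.125), with 18 of 20 negative. With an estimated correlation, which for this list (-0.024) was below the preset 0.01, the list did not pass (camera, adjusted p = 0.171). Handling at dissection could raise Atf3 and other early genes. With the immediate early score of each heart as a covariate the ATF4 targets not on that list differed by 1.03 (95% interval 0.59 to 1.47), against 1.13 without it. That score itself differed by only 0.323 between the groups (95% interval -0.138 to 0.784). With so few hearts, adjusting for it cannot exclude handling. An amino acid or mitochondrial trigger of ATF4 in hearts without Acsl1 is a hypothesis only, which none of these tests addressed. Other triggers, and the mTOR activity that the series title asks about, were not examined. An effect of the tamoxifen-activated recombinase itself also stays open, since whether the control hearts carry it is not given in the sources used here.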
